A study of Mus musculus with 16 samples.

How the data were processed

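The 16 samples comprised 12 ChIP libraries, 1 for each of 6 histone marks in WT and KO jejunal epithelial cells, and 4 input libraries (2 WT, 2 KO), which were not analysed here. Libraries were sequenced for 50 cycles, single end, and aligned to mm9, per the labels' protocols. The submitters' processing notes name CASAVA 1.8.2, Bowtie2 2.2.9, MACS2 2.1.1 and HOMER 3.12. The file headers name MACS 2.0.10.20130419 and a tag size of 75 bp, which differ from the notes and the 50 cycles, and the difference was not resolved.

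Per the file headers, regions were called with the library of the other genotype as control, at a q cutoff of 0.05, with 1 tag kept per position. The authors' lists are therefore lists of differences between 2 libraries, not lists of enriched regions. The deposited values are the pileup, a signal at the summit scaled to the smaller library, the fold (a ratio of the pileup to the local background in the other genotype), and -log10 of the p-value and of the q-value, per the file headers. They were used to describe, rank and filter regions within a list, and the rule for named genes took the highest folds of gene list members over all marks of a direction. Of 12 deposited lists, 2 (KO H3K27me3 and KO H3K4me1) repeat the regions of the WT list of the same mark, so 10 lists were used, with 23511 regions. Duplicate removal left 64.3% of WT and 56.0% of KO H3K9ac tags, the lowest shares of the 12 libraries.

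A table with the repeated H3K4me1 list gives, for the authors' nearest gene of each region, the authors' log2 fold change of RNA and its FDR, an adjusted p-value. It holds 12 further per-library columns, of 6 RNA libraries, that no calculation used. The direction of the log2 fold change was read as KO over WT from HOMER's naming of such columns, the first group named being the baseline. A few group values in those per-library columns were also looked at to settle this sign, although they were not to be used in any step. The RNA test's tool is not given in the sources used here. RNA values were joined for 1363 genes on chromosomes with regions.

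No region of any list lay on chromosome 18, where 800.4 of 23378 placed regions would fall by length. Region numbering had no gaps in any of the 10 lists. Genes of chromosomes 18 and Y were left out of the gene background, which held 21693 protein-coding genes.

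Regions were joined to GENCODE gene models of the mm9 assembly. A region belonged to the gene with the nearest transcription start within 50 kb of its summit. H3K4me1 regions belonged to the gene the authors name, with no limit on distance. For example, 1 region assigned to Ppargc1a lay 453539 bp from the nearest start. Counts of genes with H3K4me1 thus follow another rule than those of the other marks. Promoters reached 1 kb from a start. Shares carry 95% Wilson intervals, which cover counting error only. A region was shared at an overlap of at least 1 bp, and counts were compared with 1000 shuffles within each chromosome. The percentile of an overlap is the percent of shuffles below it, with ties split evenly above and below. A pair counted as above or below the shuffles at percentile 97.5 or 2.5. That call, and the treatment of ties, were chosen after values had been seen, because ratios moved with nearly every setting. For 16 gene lists fixed before the data were examined, the members with at least 1 region were counted and compared with 10000 random lists matched on 10 classes of gene length. Their percentile is the percent of random lists with fewer members. A count of 0 members therefore has percentile 0 whatever the random lists hold, and does not place a list below them. No p-value was computed, since genes and regions are not replicates.

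The genes named were fixed by rule before the data were examined: Ncor1, genes of the 5 regions with the highest -log10 p per list, the 10 genes with regions of the most active marks per direction, and up to 4 members per gene list and direction with the highest fold. This gave 121 genes. Others named were chosen after their values were seen and are given as such.

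Both statistics were tested on simulated data. With 200 shared regions planted in lists of 2000, 206 were found. Over 200 pairs of independent lists the mean percentile was 50.4 (standard error 2.07), and 7 pairs (3.50%) lay at 97.5 or above and 4 at 2.5 or below. An earlier form of this test, with 1 pair and then 40, was replaced because a single pair had crossed the threshold and the median of so coarse a percentile was uninformative. For 200 pairs of independent lists placed at promoters, the median percentile was 100 with plain shuffles, and the mean was 48.7 (standard error 2.10) with shuffles that kept the distance to a start. An earlier form of that check used 40 pairs. Lists of 25 long genes had a median percentile of 50.8 with matching and 97.7 without. Simulated regions were placed independently, whereas the 7111 KO-higher H3K27ac regions became 5940 when merged within 1 kb. Shuffles break up such clusters, so the overlap simulations do not check percentiles of clustered lists.

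Alternatives fixed in advance were a -log10 q of at least 5, a fold of at least 4, merging within 1 kb, autosomes only, covered bases, other overlap rules, shuffles within 1 Mb, a promoter of 2.5 kb, regions within 10 kb of the gene body, unmatched random lists and lists of equal length. Leaving out 3 doubted stretches, the nearest promoter for H3K4me1, matching on the stretch of genome nearest to each gene, shuffles that move each region to another transcription start of its chromosome at the same distance (from a start within 1 kb drawn at random, or else the nearest), all RNA settings and a limit on GC content (KO-higher regions at or above the WT-higher median and WT-higher regions at or below the KO-higher median of the mark) were chosen after seeing the data, as was the RNA comparison itself. The doubted stretches were the extents of KO-higher H3K9me3 regions of fold at least 4 at Vil1 and at Mt1, and a run of 100 kb windows of chromosome 17 with WT-higher regions of at least 5 marks. To describe H3K9me3 and H3K27me3 there, stretches were drawn again without them, a choice also made after seeing the data. At Vil1 the stretch was the span of KO-higher H3K4me3 regions. On chromosome 17 it was the longest run of windows in the genome with WT-higher regions of all 4 active marks. Repressive marks had already been seen at both places, so the redrawn edges give no independent test. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used.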

Results

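Chromatin of jejunal epithelial cells from C57BL/6 mouse neonates at postnatal day 12 was profiled by ChIP-seq for 6 histone marks, in wild-type (WT) mice and in mice with an intestinal deletion of NCoR1 (KO). NCoR1 is a corepressor that recruits histone deacetylase activity to nuclear receptors. H3K4me1, H3K4me3, H3K9ac and H3K27ac mark active promoters and enhancers, and H3K9me3 and H3K27me3 mark repressed chromatin. There was 1 library per mark and genotype, so no difference between genotypes could be set against replicate error, and every comparison below describes these libraries. The libraries held 27946003 to 47976125 tags, of which 23925163 to 32444815 were left after duplicates were removed. Each deposited list holds the regions where one genotype's library exceeded the other genotype's library of the same mark, and these are called WT-higher and KO-higher regions. Folds are the authors' values per region.

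The first question was in which direction each mark differed. KO-higher regions outnumbered WT-higher regions for H3K27ac (7111 against 2510) and for H3K9me3 (1816 against 574). H3K4me3 went the other way, with 4166 WT-higher and 131 KO-higher regions. H3K9ac had 2151 WT-higher and 1883 KO-higher regions. KO-higher regions thus made up 73.9% of the listed H3K27ac regions (95% Wilson interval 73.0 to 74.8), 76.0% for H3K9me3 (74.2 to 77.7), 46.7% for H3K9ac (45.1 to 48.2) and 3.05% for H3K4me3 (2.58 to 3.61). For H3K4me1 and H3K27me3 only WT-higher lists were analysed, with 2774 and 395 regions. These intervals cover counting error only. The H3K9ac share passed to the other side, 65.2%, when only regions with a -log10 q of at least 5 were kept, and the H3K4me3 share was 18.9% among regions with a fold of at least 4.

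**Figure D1:**
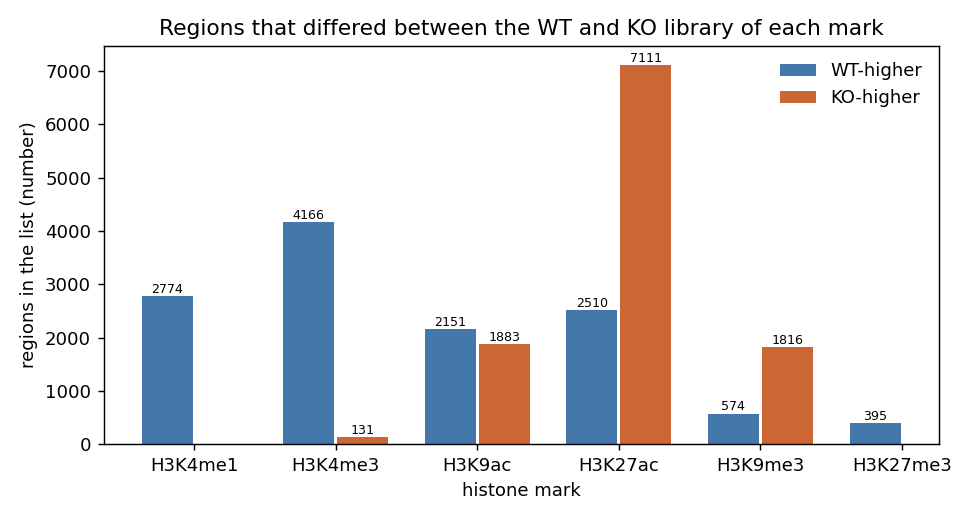
Number of regions (vertical axis) in the WT-higher and KO-higher list of each histone mark (horizontal axis), 1 library per mark and genotype. H3K27ac had 7111 KO-higher and 2510 WT-higher regions, whereas H3K4me3 had 131 and 4166.

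At Ncor1 itself (mm9 chromosome 11, 62129928 to 62272043, minus strand), no WT-higher region of any mark was assigned to the gene. Of 5 KO-higher H3K27ac regions within 50 kb of its promoters, 1 lay inside the gene, in an intron at 62226456 to 62226657, and had the highest fold, 6.04. The other 4 lay outside, upstream of the gene, between 62280042 and 62309238. They lay in introns of another gene or genes, and only the rule of the nearest start joined them to Ncor1. Histone marks do not measure the deleted sequence, so these values do not check the genotype labels. Of the other members of the corepressor complex, Tbl1x (fold 6.37) and Tbl1xr1 (fold 4.15) also had KO-higher H3K27ac. The count of 3 of 7 members was at percentile 94.8 of random gene lists of matched length. KO-higher H3K9ac lay at 2 members (96.5), WT-higher H3K9ac at 1 (43.2) and WT-higher H3K4me1 at 1 (32.8).

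WT-higher and KO-higher regions differed in where they lay. WT-higher regions were at promoters, within 1 kb of a transcription start, in 67.2% of cases for H3K4me3 (65.8 to 68.6), 47.0% for H3K9ac (44.9 to 49.1) and 37.4% for H3K27ac (35.6 to 39.3). KO-higher regions were at promoters in 13.7% (8.87 to 20.7), 15.3% (13.7 to 16.9999) and 8.01% (7.40 to 8.66) of cases. Within 2.5 kb of a start lay 72.3, 52.4 and 41.9% of these WT-higher regions and 22.1, 28.4 and 17.03% of the KO-higher ones. Introns held 50.4% of KO-higher H3K27ac and 51.9% of KO-higher H3K9ac regions. WT-higher H3K4me1 regions were at promoters in 9.63% of cases, and the repressive marks in 0.995 to 3.89%, beside 2.40% of random positions. Within 2.5 kb these shares were 17.3% and 2.16 to 8.61%. The 2 directions also differed in base composition. Median GC content was 59.5% in WT-higher and 54.9% in KO-higher H3K27ac regions, 61.6% and 54.7% for H3K9ac, 64.6% and 53.96% for H3K4me3, and 55.9% and 53.5% for H3K9me3.

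**Figure D2:**
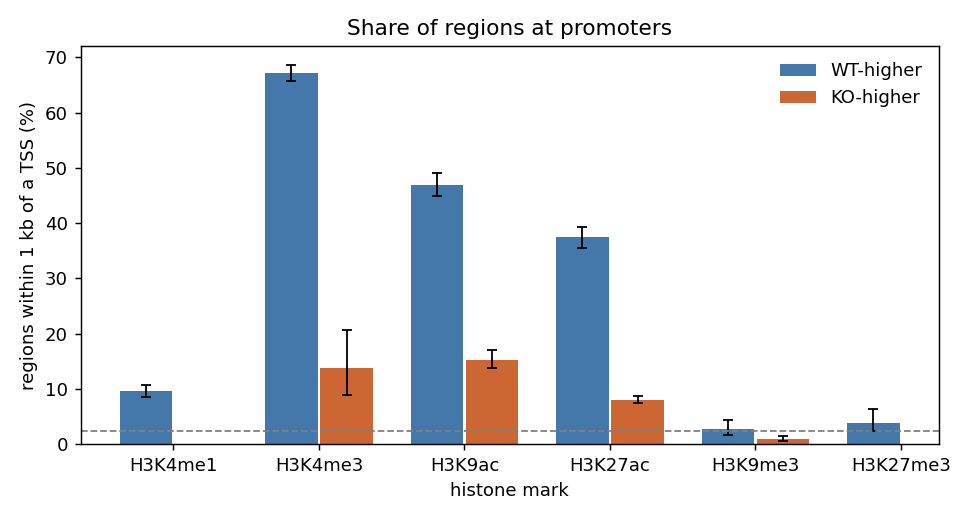
Share of regions within 1 kb of a transcription start site (TSS), in percent, for each mark and direction. Error bars are 95% Wilson intervals and the dashed line is the share of random positions, 2.40%. WT-higher H3K4me3, H3K9ac and H3K27ac regions reached 67.2, 47.0 and 37.4%, and KO-higher regions of these marks 13.7, 15.3 and 8.01%.

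The overlap of lists asked whether the same regions differed in several marks. Of 1882 KO-higher H3K9ac regions, 732 (38.9%) shared bases with a KO-higher H3K27ac region, against a mean of 2.62 in 1000 shuffles. Of 131 KO-higher H3K4me3 regions, 43 shared bases with KO-higher H3K9ac and 39 with KO-higher H3K27ac. Without the 3 doubted stretches, 35 and 30 did. On the WT side, 418 of 2148 H3K9ac regions shared bases with H3K27ac, and 423 of 4141 H3K4me3 regions with H3K9ac. Shuffled regions fall anywhere on a chromosome, so lists that both lie at promoters exceed them by location alone. All 9 pairs of active marks in the same direction also exceeded shuffles that kept each region's distance to a transcription start, by 5.33 to 222 times instead of 29.5 to 956 times. Neither kind of shuffle accounts for active chromatin away from starts. Acetylation in opposite directions did not exceed either kind: 1 WT-higher H3K9ac region met a KO-higher H3K27ac region (shuffle mean 2.80), and 1 KO-higher H3K9ac region met a WT-higher H3K27ac region (0.837). WT-higher methylation of H3K4 did meet KO-higher acetylation. Of 2751 WT-higher H3K4me1 regions, 75 shared bases with KO-higher H3K27ac (shuffle mean 3.72), 36 with KO-higher H3K9ac (0.933), 5 with KO-higher H3K4me3 (0.078) and 199 with WT-higher H3K27ac. Of 4141 WT-higher H3K4me3 regions, 25 shared bases with KO-higher H3K27ac (5.46) and 11 with KO-higher H3K9ac (1.37). Both excesses ended with a -log10 q of at least 5 (percentiles 97.2 and 84.05) and with shuffles that kept the distance to a start (92.85 and 90.4). No KO-higher H3K4me3 region met WT-higher H3K9ac or H3K27ac (percentiles 47.8 and 46.15). No region was shared by the WT-higher and KO-higher list of one mark.

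Genes of cholesterol and bile acid handling controlled by LXR and FXR had KO-higher H3K27ac, H3K9ac and H3K4me3 more often than random lists. Of 23 genes, 14 had KO-higher H3K27ac, 10 had KO-higher H3K9ac and 6 had KO-higher H3K4me3. Random lists of matched gene length averaged 2.88, 1.04 and 0.0761. They were drawn from all protein-coding genes, whether or not active in these cells. Here and for the lists below, genes active in the intestine can exceed them by that activity alone. KO-higher H3K27ac lay at 0 of 18 immune, 0 of 21 stromal and 0 of 53 Polycomb target genes (random means 2.28, 2.56, 5.46). When regions were limited by GC content, 2 KO-higher H3K4me3 regions were left in the genome. None lay at an LXR or FXR gene (percentile 0). Scd1 and Scd2, which desaturate fatty acids, had the highest H3K27ac folds (10.7 and 9.40), followed by the sterol exporters Abca1 (8.80) and Abcg1 (8.40). At Abca1 a KO-higher H3K9ac region of fold 6.67 covered the promoter (chromosome 4, 53171538 to 53172795). Srebf1, a regulator of lipid synthesis, had KO-higher regions of 3 active marks, with folds of 4.65 for H3K27ac, 4.72 for H3K9ac and 4.31 for H3K4me3. H3K4me1, also an active mark, had WT-higher regions at 7 of the 23 genes (percentile 99.7). It had no KO-higher list, so its direction at these genes could not be compared. WT-higher H3K9ac was found at 2 genes, including Fabp6 (fold 2.88), a bile acid binding protein, and WT-higher H3K27ac at 1.

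**Figure D3:**
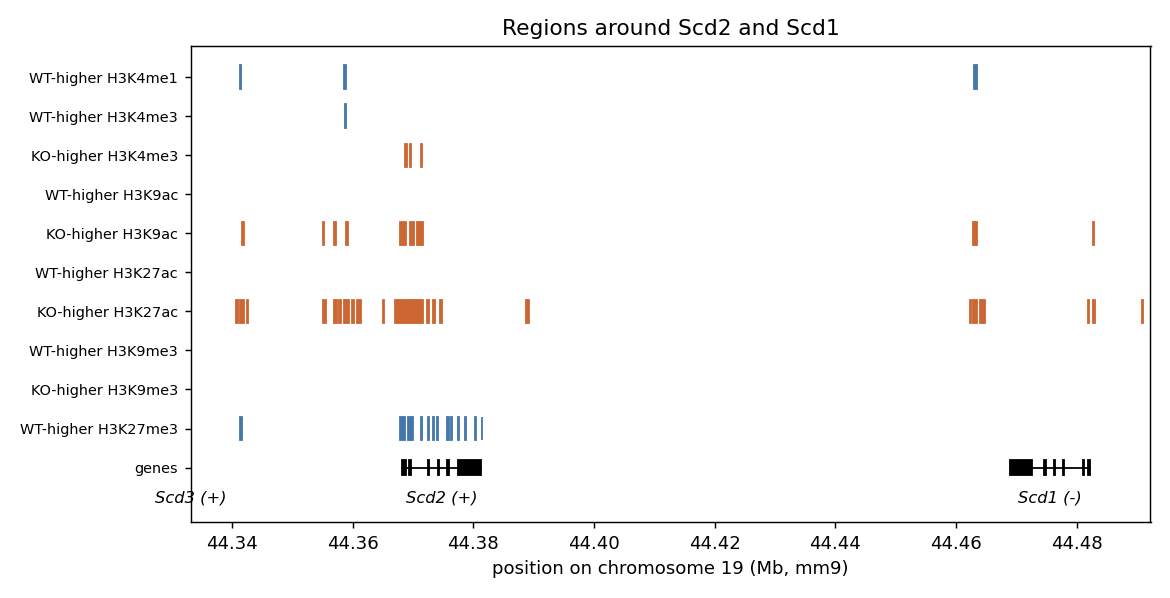
Regions around Scd2 and Scd1 on chromosome 19 (mm9, position in Mb on the horizontal axis), 1 row per list, blue for WT-higher and orange for KO-higher, with exons as black boxes. KO-higher H3K27ac and H3K9ac regions lay at both genes, and 14 WT-higher H3K27me3 regions were assigned to Scd2.

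Genes of PPAR-controlled fatty acid use also carried KO-higher acetylation, with H3K27ac at 20 of 30 genes and H3K9ac at 15 (random means 3.87 and 1.40). The examples with the highest folds included the receptor gene Ppara (H3K27ac 6.75, H3K9ac 6.69, in an intron), Pdk4, which restrains glucose oxidation (H3K9ac 7.03), and the lipid droplet gene Plin2 (H3K9ac 6.04). WT-higher H3K27ac was found at 1 member, Acadm (3.34), and WT-higher H3K4me1 at 6 (percentile 95.2). Among 23 enterocyte identity genes, 19 had KO-higher H3K27ac and 15 KO-higher H3K9ac (random means 2.61 and 0.896). They included Hnf4g, a transcription factor of enterocytes (H3K9ac 6.49), Apob, needed for chylomicrons (H3K9ac 5.89), and Krt20, a keratin of differentiated cells (H3K9ac 4.91). WT-higher H3K27ac was found at 2 members, Elf3 and Klf4. Vil1 is described separately. The KO-higher H3K4me3 count of this list was 2 members and left the 99th percentile, at 93.9, without Vil1's 5' end and 2 other doubted stretches.

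Detoxification genes had KO-higher H3K27ac at 20 of 47 members and KO-higher H3K9ac at 9 (random means 6.28 and 2.29). Examples were the cytochrome P450 genes Cyp3a13 (H3K27ac 8.17) and Cyp3a25 (H3K9ac 9.77), the exporter Abcc2 (H3K9ac 7.58) and Nfe2l2, the regulator of antioxidant genes (H3K9ac 6.65). WT-higher H3K9ac was found at 2 members. Genes of the suckling and of the adult enterocyte were both represented. Of 18 suckling genes, 8 had KO-higher H3K27ac and 5 KO-higher H3K9ac, among them lactase, Lct (H3K27ac 2.92), and Prdm1, a repressor of adult genes (H3K27ac 4.59). Of 16 adult genes, 7 had KO-higher H3K27ac and 6 KO-higher H3K9ac, among them the disaccharidase Mgam (H3K27ac 6.38) and the glucose transporters Slc5a1 (4.51) and Slc2a2 (4.15). WT-higher H3K27ac was found at 3 suckling genes, including Amn (5.96), and at 1 adult gene, Anpep, and WT-higher H3K9ac at 2 suckling and 2 adult genes. WT-higher H3K4me1 lay at 6 suckling genes (percentile 98.9; 2 genes when counted by gene body) and 3 adult genes (86.5). The suckling H3K27ac count left the 99th percentile with lists of equal length (97.4), and the adult H3K9ac count with a -log10 q of at least 5 (98.8). Thyroid hormone, vitamin D and retinoic acid targets had KO-higher H3K27ac at 10 of 25 and H3K9ac at 7, for instance Dhrs3 (H3K27ac 4.25) and Thrb (H3K9ac 6.35), and WT-higher H3K27ac at 3 and H3K9ac at 2. Inflammation genes had KO-higher H3K27ac at 7 of 24 (random mean 2.32), including Ciita (4.54) and Ifit1 (4.46), and WT-higher H3K27ac at 3. Ciita also had WT-higher H3K4me1 (4.21) and H3K4me3 (3.82). The inflammation count left the 99th percentile by gene body (87.4), with unmatched random lists (98.6) and with lists of equal length (91.4). With the limit on GC content no member was left (percentile 0). WT-higher H3K4me1 was also found at 5 of the 25 thyroid hormone, vitamin D and retinoic acid targets, 4 inflammation, 3 detoxification and 2 enterocyte identity genes (percentiles 89.7, 92.4, 17.3 and 44.75). WT-higher H3K4me3 lay at 2 to 5 genes of each of the 8 lists from LXR and FXR to inflammation, at percentiles of 0.800 to 79.4.

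In the WT direction, 2 other gene lists had a count past the 99th percentile. WT-higher H3K4me3 lay at 17 of 53 Polycomb target genes (random mean 7.11), such as Irx3 (3.29) and Pax6 (4.39), both developmental transcription factors. The Irx3 and Pax6 regions lay between genes, at 3650 and -21707 bp from the start, not at promoters. Imprinted genes had WT-higher H3K27ac at 6 of 20 (random mean 1.71), including the growth factor gene Igf2 (5.61), whose promoter region lay at chromosome 7, 149845981 to 149846161, and Dlk1 (5.30), and KO-higher H3K27ac at 3, Gnas, Grb10 and Igf2r. WT-higher H3K4me3 lay at 8 imprinted genes (percentile 98.5) and WT-higher H3K9ac at 5 (97.2). The WT-higher H3K27ac count of imprinted genes left the 99th percentile by gene body (94.3) and with random lists matched on territory (98.6). With the limit on GC content no member was left (percentile 0). Counts of the following lists did not reach the 99th percentile. Stem cell and Wnt genes had WT-higher H3K4me3 at 9 of 22 (percentile 98.1), WT-higher H3K27ac at 5 (94.6), including Znrf3 (6.07) and Myc (3.03), and KO-higher H3K27ac at 4 (65.0). Proliferation genes had WT-higher H3K4me3 at 6 of 20 (percentile 94.7) and WT-higher H3K27ac at 4 (95.6). Secretory cell genes had KO-higher H3K27ac at 2 of 29 and WT-higher H3K4me3 and H3K4me1 at 4 each. Of 18 immune cell genes, 1 had WT-higher H3K4me1 (Runx3) and 1 WT-higher H3K4me3 (Ikzf1). Of 21 stromal genes, 4 had WT-higher H3K4me3 (random mean 3.38, percentile 55.1), 2 WT-higher H3K4me1, 1 WT-higher H3K9ac and 1 KO-higher H3K9me3 (Col3a1).

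Of 160 counts (16 gene lists in 10 region lists), 20 reached the 99th percentile of random lists. When KO-higher regions were limited to those with a GC content at or above the WT-higher median, and WT-higher regions to those at or below the KO-higher median, 658 of 7094 KO-higher H3K27ac and 87 of 1882 KO-higher H3K9ac regions were left and 7 of the 20 counts remained there. The 7 were the H3K27ac counts of the LXR and FXR, PPAR and enterocyte identity lists, the H3K9ac counts of the LXR and FXR and PPAR lists, WT-higher H3K4me1 at LXR and FXR genes, which has no opposite list and was not limited, and WT-higher H3K4me3 at Polycomb targets. The Polycomb count left the 99th percentile with a -log10 q of at least 5 (87.6). With lists of equal length, which kept 131 of the WT-higher H3K4me3 regions, no member was left (percentile 0). After so large a cut, a count of 0 does not place the list below random lists.

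RNA changes were compared with the marks through the authors' deposited table, which covers genes near WT-higher H3K4me1 regions and is thus not a sample of all genes. The RNA libraries are not among the samples described here. The RNA columns used name neither age nor cells, so whether they match the ChIP material is not known from them. Of 1363 genes in the authors' deposited table, 77 were higher and 146 lower in KO at a false discovery rate (FDR) under 0.05. KO-higher H3K27ac was found at 66 of the 77 genes with higher RNA (85.7%, 76.2 to 91.8), at 11 of the 146 with lower RNA (7.53%, 4.26 to 12.99) and at 154 of the other 1140 (13.5%, 11.6 to 15.6). WT-higher H3K27ac was found at 1 of the 77, 65 of the 146 (44.5%, 36.7 to 52.6) and 221 of the 1140 (19.4%, 17.2 to 21.8). KO-higher H3K9ac lay at 46 of the 77 genes with higher RNA (59.7%), at 3 of the 146 and at 55 of the 1140 (4.82%). WT-higher H3K9ac and WT-higher H3K4me3 each lay at 63 of the 146 genes with lower RNA (43.2%, 35.4 to 51.3), at 2.60% and 12.99% of genes with higher RNA and at 14.8% and 24.2% of genes not past the FDR. With a -log10 q of at least 5 they lay at 19.9% and 21.2% of genes with lower RNA. In the authors' deposited table, the log2 fold change of KO over WT was 2.83 for Abca1 (FDR 8.6e-113), 1.85 for Scd1 (FDR 1.32e-10), 1.72 for Scd2 (FDR 1.23e-81), 1.10 for Krt20 (FDR 4.53e-20) and 0.92 for Plin2 (FDR 9.25e-29). Other named genes with KO-higher acetylation did not pass the FDR there, such as Thrb (-0.09, FDR 0.927), Cps1 (-0.09, FDR 0.79) and Rbp2 (0.14, FDR 0.536). Ephb2 was lower in KO (-0.37, FDR 0.00162), with KO-higher H3K27ac of fold 2.04 but also WT-higher H3K9ac of fold 3.16. Of 19 named genes with KO-higher acetylation in the authors' deposited table, 13 were higher, 1 was lower and 5 did not pass. Of 14 with WT-higher acetylation, 5 were lower, 0 were higher and 9 did not pass. Ephb2 and Maf had acetylation in both directions and counted in both groups. The authors' deposited table gives -1.13 for Thsd4 (FDR 4.87e-25), a gene with WT-higher regions of all 4 active marks. With regions limited by GC as above, KO-higher H3K27ac was left at 22.1% of genes with higher RNA and 3.51% of genes not past the FDR, and KO-higher H3K9ac at 9.09% and 0.526%. WT-higher H3K27ac was left at 15.1% of genes with lower RNA and 4.56% of genes not past the FDR, and WT-higher H3K9ac at 6.16% and 1.32%. For WT-higher H3K4me3 the excess at genes with lower RNA was gone, with 1.37% (2 genes, 0.376 to 4.86) and 2.46% (1.70 to 3.53). These intervals overlap, so a turned order is not shown.

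**Figure D4:**
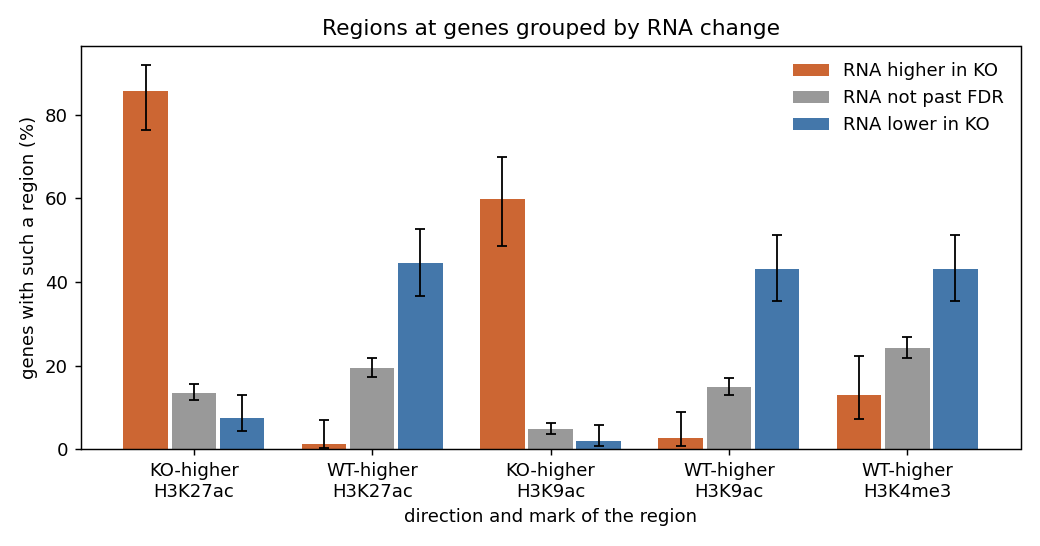
Share of genes, in percent, with a region of the given direction and mark, for 77 genes with RNA higher in KO, 146 lower in KO and 1140 not past the authors' FDR of 0.05. Error bars are 95% Wilson intervals. KO-higher H3K27ac was found at 85.7% of genes with higher RNA and 7.53% of genes with lower RNA.

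A few stretches of DNA stood apart because marks of opposite kinds moved together. Over the 5' end of Vil1, the gene of the microvillus protein villin, KO-higher H3K4me3 regions spanned 74448567 to 74461709 on chromosome 1 (13143 bp). KO-higher regions of H3K4me3, H3K9ac, H3K27ac and H3K9me3 covered 83.3, 63.6, 84.4 and 82.2% of this span, with highest folds of 50.9, 11.5, 12.7 and 71.03, each a value of its own list. Another 3 KO-higher H3K27ac regions at Vil1 lay outside it. At Mt1, a metallothionein gene, an H3K9me3 region at chromosome 8, 96703140 to 96704440, had a fold of 85.1, beside KO-higher H3K4me3 of 2.79 and H3K27ac of 2.28. In the other direction, the longest run of 100 kb windows with WT-higher regions of all 4 active marks lay between 6251783 and 6550557 on chromosome 17. It held WT-higher regions of all 6 marks around Dynlt1b and Tmem181b-ps, from 11 regions for H3K9me3 to 55 for H3K4me1. In the authors' deposited table, RNA of Dynlt1b did not pass the FDR (log2 fold change -0.18, FDR 1).

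**Figure D5:**
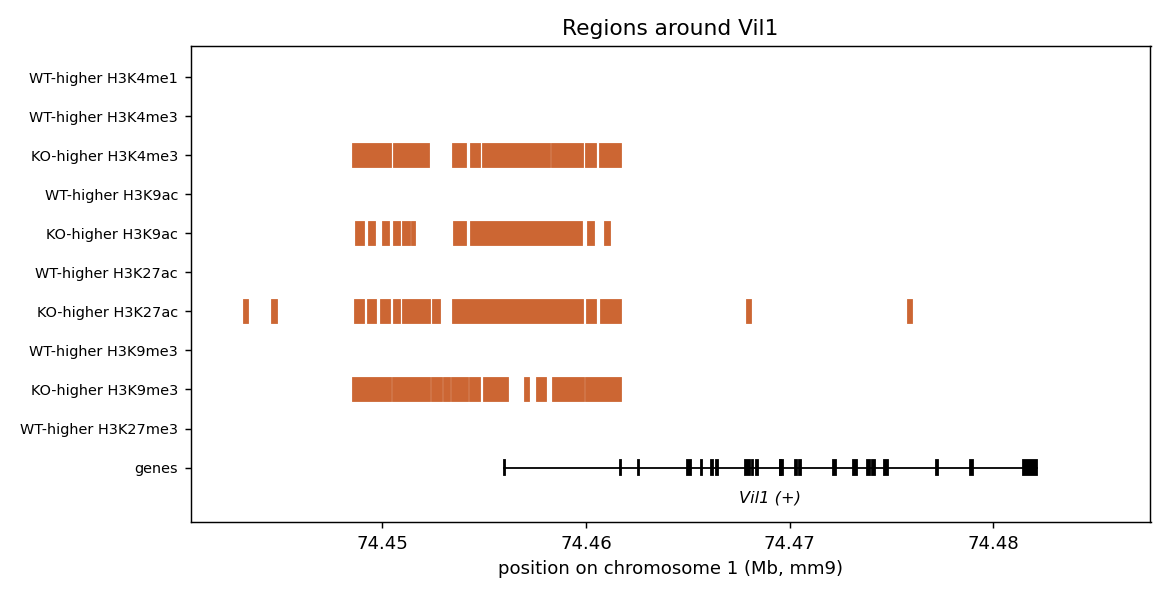
Regions around Vil1 on chromosome 1 (mm9, position in Mb on the horizontal axis), 1 row per list, with exons of Vil1 as black boxes. KO-higher regions (orange) of H3K4me3, H3K9ac, H3K27ac and H3K9me3 covered 83.3, 63.6, 84.4 and 82.2% of the span of the H3K4me3 regions, 74448567 to 74461709.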

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

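The settings without the 3 doubted stretches, with shuffles keeping the distance to a start, with the limit on GC content, with territory matching and all RNA settings were chosen after seeing the data. With 1 library per mark and genotype, other differences between the libraries of a pair are confounded with genotype. Depth after filtering was nearly equal for H3K27ac (32095696 WT and 31846932 KO tags) and H3K9me3 (24523446 and 23925163). The KO library was deeper for H3K4me1 (27718038 and 32444815), H3K4me3 (24880783 and 29097769) and H3K9ac (24263055 and 26868121), and the WT library for H3K27me3 (29529074 and 25162338). No paired analysis was possible because each group has 1 library. Covered bases were compared as shares, not for list sizes.

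With a -log10 q of at least 5, WT-higher lists held 1199 (H3K4me1), 1483 (H3K4me3), 640 (H3K9ac), 1287 (H3K27ac), 199 (H3K9me3) and 83 (H3K27me3) regions, and KO-higher lists 61 (H3K4me3), 1198 (H3K9ac) and 508 (H3K9me3). With a fold of at least 4 they held 591, 347, 488, 364, 248 and 209, and 81, 407, 1155 and, for H3K27ac, 761. Smaller lists follow from these filters. The KO share of H3K9ac reversed to 65.2% with the q filter and was 43.4% after merging. The KO share of H3K4me3 was 3.95% with the q filter, 18.9% with the fold filter and 3.97% of covered bases. For H3K27ac it was 79.4, 67.6 and, after merging, 72.1%, and for H3K9me3 71.9% with the q and 82.3% with the fold filter. The cause was not tested. With a promoter of 2.5 kb, which takes in more sequence, promoter shares of WT-higher regions were 17.3 (H3K4me1), 72.3 (H3K4me3), 52.4 (H3K9ac), 41.9 (H3K27ac), 5.76 (H3K9me3) and 8.61% (H3K27me3), and of KO-higher regions 22.1 (H3K4me3), 28.4 (H3K9ac), 17.03 (H3K27ac) and 2.16% (H3K9me3).

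Of 222 overlap values under alternatives, 203 kept their side of the threshold, 12 moved back within the shuffles and 7 moved outside them. The 9 same-direction pairs of active marks stayed above it in all settings, but their ratios to the shuffles moved: 29.5 to 956 as reported, 9.91 to 200 within 1 kb, 13.2 to 130 with shuffles within 1 Mb, 5.33 to 222 with shuffles keeping the distance to a start and 34.1 to 1750 with the q filter. Without the doubted stretches, KO-higher H3K9me3 no longer stood above the shuffles with KO-higher H3K27ac (percentile 57.8) or H3K9ac (31.9), nor WT-higher H3K4me1 with WT-higher H3K9me3 (40.55, 0 shared regions instead of 6) or H3K27me3 (93.2, 1 instead of 11). WT-higher H3K9ac lay below the shuffles with KO-higher H3K27ac within 1 kb (0.35) and with shuffles keeping the distance to a start (0.1).

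Of 20 shares of regions on chromosome X under alternatives, 3 moved, all with the q filter: to 2.72% for WT-higher H3K4me3, 3.28% for KO-higher H3K4me3 and 17.4% for WT-higher H3K27me3.

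Of the 20 gene list counts at the 99th percentile, 17 to 20 stayed there under each setting other than the limit on GC, which left 7. That limit took xenobiotic H3K27ac to 86.0 and H3K9ac to 80.4, suckling H3K27ac to 91.8 and H3K9ac to 92.1, adult H3K27ac to 93.7, and thyroid, vitamin D and retinoic acid H3K27ac to 97.3 and H3K9ac to 89.5. Enterocyte identity H3K9ac and H3K4me3, LXR and FXR H3K4me3, adult H3K9ac, inflammation H3K27ac and imprinted H3K27ac went to 0. A percentile of 0 here means that no member was left, not that random lists held more. The limit keeps few regions, such as 87 KO-higher H3K9ac and 2 KO-higher H3K4me3 regions. Other losses were inflammation (87.4 by gene body, 98.6 unmatched, 91.4 with equal lists), imprinted H3K27ac (94.3 by gene body, 98.6 by territory), adult H3K9ac (98.8 with the q filter), suckling H3K27ac (97.4 with equal lists), and Polycomb targets (87.6 with the q filter, 0 with equal lists of 131 regions), and enterocyte identity H3K4me3 (93.9 without the doubted stretches).

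Shares of genes with a region, among genes with RNA higher in KO, lower in KO and not past the FDR, moved as follows, and the cause was not tested. With the GC limit they were 22.1, 2.74 and 3.51% for KO-higher H3K27ac, 0, 15.1 and 4.56% for WT-higher H3K27ac, 9.09, 0 and 0.526% for KO-higher H3K9ac, 0, 6.16 and 1.32% for WT-higher H3K9ac, and 0, 1.37 and 2.46% for WT-higher H3K4me3. With the q filter, WT-higher H3K9ac was at 0, 19.9 and 5.53% and WT-higher H3K4me3 at 6.49, 21.2 and 9.56%, WT-higher H3K27ac at 32.9% of lower and 11.7% of other genes, KO-higher H3K9ac at 46.8% of higher and 3.60% of other genes, and KO-higher H3K27ac at 11.1% of other genes. With a log2 fold change of at least 1, which left 11 and 37 genes, KO-higher H3K9ac was at 81.8, 0 and 7.22%, KO-higher H3K27ac at 0% of lower and 16.9% of other genes, and WT-higher H3K27ac and WT-higher H3K9ac each at 0% of higher and 54.1% of lower genes. KO-higher H3K9ac was at 72.1% of genes with higher RNA at an FDR under 0.01, and WT-higher H3K4me3 at 26.9% of other genes by gene body. The other 53 of 90 RNA values lay within the reported intervals.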

Other observations

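The tests of explanations in this part were chosen after the result was seen, except the GC content tests of H3K27ac and H3K9ac, whose predicted outcomes were written before any GC value was computed. Scd2 carried opposite marks. Of KO-higher regions that shared bases with a WT-higher H3K27me3 region, Scd2 held 3 of 3 for H3K4me3, 4 of 5 for H3K9ac and 6 of 8 for H3K27ac. The others were at Scd3, with 1 each for H3K9ac and H3K27ac, and at Dmrt3, with 1 for H3K27ac. Scd3 and Dmrt3 were chosen after their values were seen. The WT-higher H3K27me3 region with the highest fold there, 6.51, lay over the Scd2 promoter (chromosome 19, 44367906 to 44368675). In the authors' deposited table, RNA of Scd2 had a log2 fold change of 1.72.

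Chromosome X, 6.33% of the genome, held 14.03% of WT-higher and 9.12% of KO-higher H3K9me3 regions and 12.8% of WT-higher H3K27me3 regions. It held 0.638 to 3.26% of the lists of active marks, except KO-higher H3K4me3, with 6.87% from 9 regions, which was 3.28% with a -log10 q of at least 5, a filter fixed in advance. Chromosome 18 held 0 regions where 800.4 would fall by length, with 515 protein-coding genes. A sequence outside the mouse chromosomes, named in the files after UGT1A, held WT-higher regions of all 6 marks: 35 of H3K27me3, 17 of H3K4me1, 10 of H3K9me3, 9 of H3K4me3, 3 of H3K27ac and 2 of H3K9ac. It also held 1 KO-higher H3K9ac and 12 KO-higher H3K27ac regions. Of these 12, 8 shared bases with WT-higher H3K4me1, 6 with WT-higher H3K27me3, and 1 each with WT-higher H3K4me3 and H3K9me3.

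KO-higher regions over the 5' end of Vil1 and at Mt1 were weighed first. In the span of KO-higher H3K4me3 at Vil1, drawn without H3K9me3, KO-higher H3K9me3 regions lay at 1179 times their genome-wide density. Marks higher in KO there were thus not only active ones. The place was singled out because these marks moved together, so the density does not test more active chromatin in KO cells as the cause. Extra copies of this DNA in the KO mice remain open. H3K9me3 covered 82.2% of that span with edges within 1 kb of its ends, a criterion set after the regions had been seen. This coverage thus does not test extra copies either, and the input libraries were not analysed. At Mt1 there was no KO-higher H3K9ac region. A candidate source is a transgene carrying Vil1 and Mt1 sequence, such as a villin-promoter Cre construct, which the labels do not name and which was not tested.

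The WT-higher stretch of chromosome 17 was drawn from the 4 active marks alone, which leaves H3K9me3 and H3K27me3 to be described in it. WT-higher regions of these marks lay at 164 and 694 times their genome-wide density. Marks higher in WT there were thus not only active ones. They had been seen there before the stretch was redrawn, so the densities do not test more active chromatin in WT cells as the cause. More copies of this DNA in the WT mice remain a candidate explanation. Here 2 of these 2 repressive marks exceeded 10 times their density, a limit set after they had been seen there. The densities thus do not test more copies either, and the input libraries were not analysed. A difference in strain background was not tested.

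WT-higher acetylation was at promoters more often than KO-higher acetylation. Over 10 kb away lay 46.3% of WT-higher and 55.4% of KO-higher H3K27ac regions, and 34.3% and 42.1% of H3K9ac regions. A difference in ChIP efficiency stays open for H3K27ac, H3K9ac and H3K4me3: the smaller list held 26.1, 46.7 and 3.05% of regions, but libraries scaled to the same total can differ in both directions under it, so these shares decide nothing. A GC bias between libraries also stays open: over 10 kb from promoters, the GC difference was still 0.594 (95% bootstrap interval 0.509 to 0.676) of that over all regions for H3K27ac and 0.540 (0.468 to 0.625) for H3K9ac. For H3K4me3 it was 0.260 (0.148 to 0.344), with 76 KO-higher regions that far away, which leaves a GC bias open there too. The genotype itself stays open too, and regulatory regions of different GC content could give the same values, which was not tested.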
